A study of Mus musculus with 30 samples.

How the data were processed

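The samples were laser captures of IML, LMN and MMN motoneurons from the spinal cords of 5 adult sham-operated mice. Per the labels, 400 captures were collected for each cell type and their RNA was extracted with a kit. The RNA was then divided in 2, each portion was amplified in a double-round protocol, and each target was hybridised to its own Affymetrix mouse array. The deposited values are intensity values on a linear scale. Per the labels, the authors normalized the signals with a tool named as R-pack and then took inverse logs; its method and version are not given in the sources used here. No detection calls or scanner values were used here, so a low value cannot be set against background. Amplification in 2 rounds from few cells favours the 3' ends of transcripts and adds spread between targets, which the paired arrays of each sample measure. Array medians ran from 131.69 to 145.908 and single values from 6.46 to 21091.8. The arrays limit the precision through their number.

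The table held 12488 probe sets. The 66 control probe sets were left out and 12422 were tested. Of these, 10833 had 1 gene symbol, 396 several and 1193 none in the platform's annotation. For 10817 the symbol was taken through the gene identifier from a table of the GRCm38.p6 assembly, whether or not it changed. No coordinates are given, because the array annotation states no build. Probe sets with several symbols stayed in the tests and were not named. The 8251 genes were each represented by the probe set with the highest mean. Of the called genes with several probe sets, other probe sets had a difference of opposite sign in 58 of 202 between IML and somatic samples, and 1 gene was called in both directions. Probe sets whose names end in _f_at, _g_at, _i_at, _r_at or _s_at, such as those used for Penk, Anxa1, Gap43, Igf2 and Prph, can bind related transcripts.

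Values were taken to log2 with no offset and the 2 arrays of each animal and pool were averaged, which gave 15 samples. Linear models were fitted with limma 3.58.1 in R 4.3.3, with the pool and the animal as fixed terms over all 15 samples, followed by eBayes. The contrasts were IML less the mean of LMN and MMN, IML less LMN, IML less MMN, and LMN less MMN. Tests were two-sided, with Benjamini-Hochberg adjustment over all 12422 probe sets and a threshold of 0.05. Errors of differences are standard errors from this model and SDs are over 5 animals. Gene lists were tested with camera with a correlation of 0.01 between genes, adjusted over all 34 lists of a contrast, and again with the correlation estimated from each list. With the estimated correlation no list was called in either contrast, and the smallest adjusted p was 0.173 between IML and somatic samples and 0.194 between LMN and MMN. The labels state that all 3 pools came from each animal, so the animal was a block. In a check of this pairing, samples of the same animal deviated from their pool means together in all 15 pairs, with correlations of at least 0.288.

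The 26 gene lists and 8 cell type lists, the main model, most other models and the rule for named genes were fixed before the data were examined. The meningeal and fibroblast covariate, the Slc18a3 covariate, the fit without suffixed probe sets and the fit without the LMN sample of animal 2 were chosen afterwards. The rule took, among probe sets with an adjusted p under 0.05, the 12 highest and 12 lowest differences between IML and somatic samples and between LMN and MMN, and the 5 highest and 5 lowest in the other contrasts. A gene needed the same sign in 5 of 5 animals and a mean in the higher side at or above the median over probe sets, 7.10. With under 5 passing genes, the 5 highest and 5 lowest by moderated statistic over the brightest probe set of each gene were added as values. Up to 4 members with the smallest p were named from each list, and Chat, Slc18a3, Slc5a7, Isl1, Prph, Nos1 and Calca were always named where measured.

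The steps were tested on simulated data with the real means, animal effects and residual spread, drawn independently between probe sets. In 5 runs over 12422 probe sets, with 500 changes of each of 2 sizes in IML over all runs, the contrast of IML with somatic samples recovered 82.8% of the log2 changes of 0.5 and 97.6% of the changes of 1, and 4.64% of its calls were false. A list of 37 genes shifted by 0.3 was called in 5 of 5 runs. The alternatives left out the block, made it random, used 1 technical set or all 30 arrays, and rescaled the arrays. They also left out dim probe sets, set a floor of 32, changed the variance model or the threshold, added marker means as covariates, kept 2 pools in the fit, and left out each animal in turn.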

Results

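Transcript levels were measured in 3 pools of spinal motoneurons taken by laser capture from the adult mouse spinal cord. The first pool came from the intermediolateral column (IML), the cell column of the autonomic preganglionic motoneurons that drive the viscera. The other 2 pools were somatic motoneurons, which innervate skeletal muscle, and came from the lateral (LMN) and the medial (MMN) motor columns. Each pool was collected from the same 5 sham-operated animals, and the RNA of each animal and pool was hybridised to 2 arrays. There were thus 10 arrays and 5 biological samples per pool, or 30 arrays and 15 samples in all. The number of animals limits the precision. Values are log2 intensities, and every n is a number of animals. The comparisons asked which transcripts part autonomic from somatic motoneurons and which part the 2 somatic pools.

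The neuropeptide genes Tac1 and Adcyap1 had the largest differences among the named genes that were higher in IML than in somatic motoneurons. S100a6 (1.64) and Lyz2 (1.58), described below with connective tissue and macrophage markers, came next, ahead of the neuropeptide gene Penk. Adcyap1, which encodes the neuropeptide PACAP, was higher by 1.81 ± 0.19 (log2, SE, n = 5), a 3.50-fold difference, with an adjusted p of 0.000901 and the same sign in 5 of 5 animals. Its mean was 9.42 ± 0.72 (SD, n = 5) in IML, 7.39 ± 0.97 in LMN and 7.83 ± 0.62 in MMN. Tac1, the substance P precursor, was higher by 2.14 ± 0.52 (adjusted p = 0.0397), and Penk, the enkephalin precursor, by 1.54 ± 0.25 (adjusted p = 0.00831). Scg2, a secretory granule protein, was higher by 0.54 ± 0.09. Of the 7 measured visceral motoneuron markers, 3 were called higher (Adcyap1, Penk and Tac1), none lower and 4 were not called, against 4 higher when adjusted over the list alone. The list as a set was shifted up by a mean of 0.92 in 5 of 5 animals (camera adjusted p = 0.00619), with an adjusted p = 0.233 with an estimated correlation. The set's mean was 0.81 when probe sets with suffixes in their names were left out (adjusted p = 0.0532), among them the one of Penk, 0.81 with glial markers as a covariate (adjusted p = 0.0524) and 0.90 with the mean of the meningeal and fibroblast markers as a covariate (adjusted p = 0.0642), and these 3 adjusted p missed the threshold. The first and the last of these models were chosen after seeing the data. Tac1 passed in 1 of the 5 fits that left out 1 animal, with differences from 1.46 to 2.48 and adjusted p from 0.0386 to 0.129. Nos1, the neuronal nitric oxide synthase, differed by 0.01 ± 0.05 and was not called. Without detection calls it is unknown whether its probe set detects the transcript, so this small difference does not show equal levels. Among 27 neuropeptide genes, 5 were called higher, none lower and 22 were not called, against 6 higher and 1 lower when adjusted over the list alone. That list as a set missed the threshold (adjusted p = 0.0703).

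Gap43, Reln and Zic1 were also among the 12 highest. Gap43, a growth cone protein, was higher in IML by 1.32 ± 0.23, Reln, the secreted protein reelin, by 1.31 ± 0.21 and the zinc finger transcription factor Zic1 by 1.30 ± 0.22, each in 5 of 5 animals. Hpca, the neuronal calcium sensor hippocalcin, was higher by 0.88 ± 0.07 (adjusted p = 0.000447). Among 27 immediate early, injury and regeneration genes, 3 were called higher (Adcyap1, Basp1 and Gap43), none lower and 24 were not called, against 5 higher when adjusted over the list alone. The set as a whole was not called (adjusted p = 0.102). Fabp7, a fatty acid binding protein of radial glia and astrocytes, was higher by 1.30 ± 0.27, and was the 1 called gene of the 14 in the astrocyte list, against 3 higher when adjusted over the list alone. That list was not called as a set (mean 0.17, adjusted p = 0.371), and its mean was 0.12 without animal 1.

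Nefh, the heavy neurofilament subunit, was lower by a log2 difference of -0.83 ± 0.09, with means of 11.56 in IML, 12.58 in LMN and 12.20 in MMN. Sh3bgr differed by -0.96 ± 0.10 (adjusted p = 0.000968), Thrsp by -0.92 ± 0.11, the transcriptional repressor Bcl6 by -1.17 ± 0.20 and the homeobox gene Irx3 by -0.97 ± 0.14, each lower in 5 of 5 animals. Tpd52l1 (-1.25), Lcp1 (-1.02), 1110008P14Rik (-0.98), Wfs1 (-0.91), Dffa (-0.89), Clvs1 (-0.83) and Mcam (-0.77) completed the 12 lowest. Of 4 measured skeletal alpha motoneuron markers, Bcl6 and the matrix metalloproteinase Mmp9 (-0.77 ± 0.15) were called lower, none higher and 2 were not called, the same counts as when adjusted over the list alone. The 4 markers as a set missed the threshold (adjusted p = 0.0675). The 25 genes of neurofilaments and the axonal cytoskeleton were shifted down as a set (mean -0.19, adjusted p = 0.00371), with an adjusted p = 0.565 with an estimated correlation. In that list Nefh and Nefl (-0.34 ± 0.09) were called lower, Stmn1 (0.51 ± 0.07) and Stmn4 (0.45 ± 0.09), which encode microtubule-destabilising stathmins, were called higher, and 21 were not called. Adjusted over the list alone, 2 were higher and 6 lower. The set's call ended with glial markers as a covariate (mean -0.09, adjusted p = 0.296) and with Slc18a3 as a covariate (mean -0.06, adjusted p = 0.516).

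**Figure D1:**
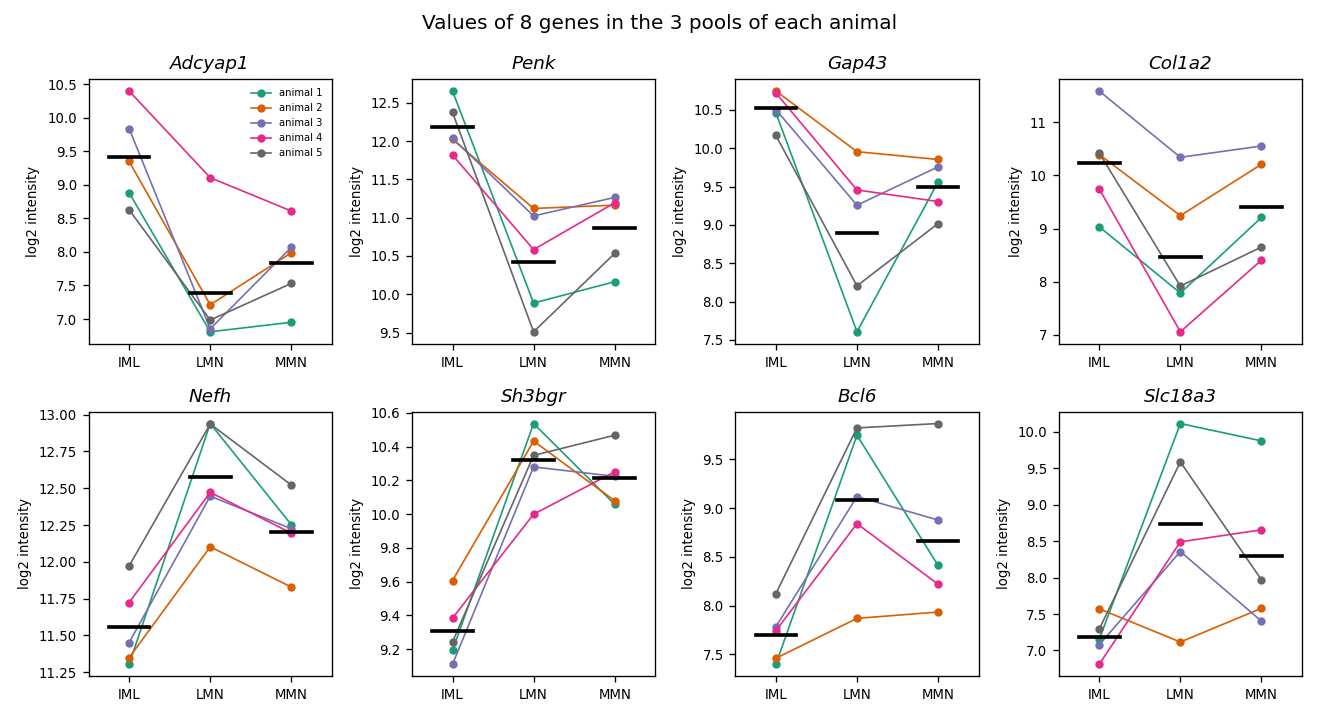
Log2 intensity (vertical axes, scaled to each gene) of 8 genes in the IML, LMN and MMN pools (horizontal axes). Each coloured line joins the 3 pools of 1 animal, each point is the mean of 2 arrays and the black bars are means over 5 animals. Adcyap1, Penk, Gap43 and Col1a2 had higher means in IML, Nefh, Sh3bgr and Bcl6 had lower means there, and Slc18a3 lay near 7.18 in IML with a wide spread between animals in LMN and MMN.

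Genes of the 3 channel lists, which also hold auxiliary and associated factors, moved in both directions in IML. Of 42 potassium channel genes, Kcna1 (-0.77 ± 0.12) and the channel subunit Kcnab1 (-0.71 ± 0.08) were called lower, Kcna5 (0.44 ± 0.08) was called higher and 39 were not called, with the same counts when adjusted over the list alone. Of 12 genes in the calcium channel list, the auxiliary members Cacna2d3 (-0.71 ± 0.10) and Cacng2 (-0.47 ± 0.12) were called lower and none higher. Adjusted over the list alone, 2 were lower and 1 higher. Of 12 sodium and HCN channel genes, Fgf11, a channel-associated factor of the fibroblast growth factor family, differed by -0.59 ± 0.06 (adjusted p = 0.000901). In the same list Scn8a, a sodium channel of the axon initial segment, differed by -0.43 ± 0.11, and Fgf13 was called higher by 0.19 ± 0.04. Adjusted over that list alone, 3 were lower and 1 higher. None of these 3 channel lists was called as a set (adjusted p = 0.147, 0.102 and 0.550).

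Slc18a3, the vesicular acetylcholine transporter, had a mean of 7.18 ± 0.28 in IML, near the median of 7.10 over all probe sets, against 8.73 ± 1.17 in LMN and 8.30 ± 1.01 in MMN. Its difference between IML and somatic samples of -1.33 ± 0.36 missed the threshold (adjusted p = 0.0579, higher in IML in 1 of 5 animals). Prph, which encodes the intermediate filament peripherin, differed by -0.60 ± 0.34 and Isl1, a motoneuron transcription factor, by 0.14 ± 0.09, and neither was called. The Isl1 values in LMN ran from 5.46 to 5.96, below the median over probe sets. The probe set may not detect the transcript, so its small difference does not show equal levels. The LMN sample of animal 2 had Slc18a3 at 7.12 and Prph at 8.19, the lowest LMN values of both. Chat, Slc5a7 and Calca had no named probe set here. Of 4 cholinergic genes, Slc44a1, a choline transporter, was called higher (0.48 ± 0.10) and 3 were not called, against 1 higher and 1 lower when adjusted over the list alone. Of 7 motoneuron identity genes, the receptor gene Ret was called lower (-0.34 ± 0.07) and 6 were not called, against 2 lower when adjusted over the list alone. Neither list was called as a set (adjusted p = 0.875 and 0.363).

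Markers of connective tissue and macrophages were higher in IML together with the genes above. All 10 measured meningeal and fibroblast markers had a positive difference, 7 were called higher and 3 were not called, against 8 higher when adjusted over the list alone. Their mean was higher by 0.98 in 5 of 5 animals (camera adjusted p = 6.61e-08), with an adjusted p = 0.173 with an estimated correlation. Lum, an extracellular matrix proteoglycan, was higher by 1.51 ± 0.33, Col1a2 by 1.30 ± 0.23, Col1a1 by 1.28 ± 0.23 and Igf2 by 1.18 ± 0.21. Of 14 microglia and macrophage markers, 7 were called higher, among them the lysozyme gene Lyz2 (1.58 ± 0.31), Tyrobp (0.79 ± 0.13), Csf1r (0.48 ± 0.07) and C1qc (0.33 ± 0.06). None was lower and 7 were not called, against 8 higher when adjusted over the list alone. Their mean was higher by 0.39 (adjusted p = 4.02e-05), with an adjusted p = 0.466 with an estimated correlation. S100a6 (1.64 ± 0.39) and Anxa1 (1.48 ± 0.31), which are abundant in fibroblasts and leukocytes, were also among the 12 highest. With the meningeal and fibroblast covariate, a model chosen after seeing the data, S100a6 turned to -0.53 and Lum, a member of the covariate, to -0.59, and neither was called. The 15 oligodendrocyte and myelin markers were higher by a mean of 0.19 (adjusted p = 0.0390), with an adjusted p = 0.565 with an estimated correlation, and only Gsn (1.12 ± 0.21) was called in that list, also when adjusted over the list alone. The set's call held in 11 of 22 alternatives, and ended without animal 1, 2 or 5 (means 0.15, 0.20 and 0.13, adjusted p = 0.146, 0.0696 and 0.192) and without the animal as a block (mean 0.19, adjusted p = 0.0760). Without animal 4 the mean was 0.30. Markers of endothelium and mural cells (mean 0.21, adjusted p = 0.111), inhibitory interneurons (mean 0.04, adjusted p = 0.550), excitatory interneurons (mean -0.17, adjusted p = 0.550) and red blood cells (mean 0.53, adjusted p = 0.0915) were not called as sets. The red blood cell list had 1.93 in animal 3, and without that animal its mean was 0.18. Without each animal in turn the means ran from 0.10 to 0.36 for endothelium, from -0.05 to 0.09 for inhibitory and from -0.26 to -0.13 for excitatory interneurons. In these 4 lists Vwf, the von Willebrand factor of endothelium (1.30 ± 0.29), was the 1 gene called. Adjusted over each list alone, 2 endothelial and 2 red blood cell markers were higher and 2 excitatory interneuron markers lower.

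Receptor, synaptic and signalling lists were not called as sets between IML and somatic samples, while single members were. Of 35 genes of synaptic vesicles and release, 5 were called higher, among them Syt5 (0.50 ± 0.05), Syt17 (0.49 ± 0.09) and Vamp3 (0.54 ± 0.11), 3 lower, among them Syt3 (-0.33 ± 0.06), and 27 were not called (set adjusted p = 0.680), against 8 higher and 10 lower when adjusted over the list alone. Of 22 calcium binding and buffering genes, Hpca was called higher, Calb2, which encodes calretinin (-0.72 ± 0.14), and Ryr2 (-0.37 ± 0.08) lower, the same counts as over the list alone. That set (adjusted p = 0.550) had a mean above 0 and a median and test below 0. Of 23 neurotrophic factor receptors, Il6st (0.69 ± 0.13) and Osmr (1.18 ± 0.29) were called higher and Ret lower, against 3 higher and 1 lower when adjusted over the list alone. With the meningeal and fibroblast covariate Il6st turned to -0.0082 and Osmr to -0.20, and neither was called. Its mean was above 0 and its median below 0 (set adjusted p = 0.733). Gphn, the glycine receptor scaffold gephyrin (-0.40 ± 0.07), was the 1 called of 12 GABA and glycine receptor genes (set adjusted p = 0.0675), against 2 lower when adjusted over the list alone. Of 45 axon guidance genes, Epha7 (0.47 ± 0.12) was called (set adjusted p = 0.371), and none was when adjusted over the list alone. Of 17 glycolysis genes, Ldha (0.70 ± 0.15) and Hk2 (0.39 ± 0.08) were called higher, also when adjusted over the list alone, while the set had a mean of -0.08 (adjusted p = 0.204), which ran from -0.13 to -0.03 without each animal in turn. B2m, the light chain of MHC class I (0.86 ± 0.11), was the 1 called of 13 antigen presentation genes, also when adjusted over the list alone (set adjusted p = 0.236). No member was called among 4 gamma and slow motoneuron markers (set adjusted p = 0.363), 18 Hox genes of groups 4 to 9 (0.453), 8 of groups 10 to 13 (0.202), 13 glutamate receptors (0.457), 18 monoamine receptors (0.996) and 7 acetylcholine receptors (0.733). Adjusted over each list alone, 2 of the Hox genes of groups 10 to 13 were lower and none of the others passed. The monoamine receptors had a mean above 0 and a median and test below 0.

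Housekeeping gene groups shifted by small amounts between IML and somatic samples. Of 34 cytosolic ribosomal protein genes, 29 had a positive difference, 3 were called higher (Rps4x, 0.54 ± 0.11; Rpl7, 0.25 ± 0.06; Rps19, 0.38 ± 0.10) and 31 were not called, against 13 higher when adjusted over the list alone. Their mean was higher by 0.16 in 5 of 5 animals (adjusted p = 5.53e-05), with an adjusted p = 0.173 with an estimated correlation. Of 70 oxidative phosphorylation genes, 65 had a negative difference, with a mean of -0.15 (adjusted p = 2.72e-07) and an adjusted p = 0.565 with an estimated correlation. In that list Cycs (-0.28 ± 0.05) and Atp5c1 (-0.33 ± 0.07) were called lower, also when adjusted over the list alone, and 68 genes were not called. The set's mean was -0.46 in animal 3 and 0.01 in animal 1. It was -0.07 without animal 3, and with the meningeal and fibroblast covariate it turned to 0.0311 (adjusted p = 0.816). The 37 proteasome genes had a mean of -0.11 (adjusted p = 0.00371), with an adjusted p = 0.565 with an estimated correlation and a mean of -0.07 (adjusted p = 0.105) without animal 3. That call also ended with technical set 1 alone (mean -0.07, adjusted p = 0.0955) and with the glial (mean -0.05, adjusted p = 0.341) and the meningeal and fibroblast (mean -0.08, adjusted p = 0.131) covariates. In that list Psmd8 (-0.29 ± 0.07) alone was called lower, and none was when adjusted over the list alone.

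In all, 686 of 12422 probe sets differed between IML and the mean of the 2 somatic pools, 427 higher and 259 lower in IML. Of the 686, 642 had the same sign in 5 of 5 animals, and 46 differed at least 2-fold, 42 higher and 4 lower. A call in this contrast need not hold against each somatic pool, since IML against LMN called 1116 and IML against MMN 43. In camera, 8 of 34 lists were called, 5 up and 3 down, and none with an estimated correlation (smallest adjusted p = 0.173). The model held the animal as a block. Without the animal as a block, 46 probe sets were called. With the mean of the meningeal and fibroblast markers as a covariate, 0 were called by limma, against 686 in the main model. The main model had 2574 at an unadjusted p under 0.05. The covariate model was chosen after seeing the data and raised the median SE by 2.35 times. The design alone, where the marker mean overlaps with the pools, gives 2.38 times. The loss of calls thus does not show by itself that connective tissue accounts for the differences. In that model 22 of the 24 genes named by size kept their sign. Adcyap1 (1.84 ± 0.46), Penk (2.06 ± 0.60) and Nefh (-0.93 ± 0.23) stayed at least as large as in the main model with larger errors, while Lyz2 (0.04 ± 0.56), Anxa1 (0.09 ± 0.61) and Col1a2, a member of the covariate (0.11 ± 0.40), came near 0. Tac1, the largest of the named differences in the main model, fell from 2.14 ± 0.52 to 0.81 ± 1.22. The count was 386 without animal 1, 169 without animal 3, 397 without animal 4 and 164 without animal 5, and of the 24 genes named by size 8 (Adcyap1, Clvs1, Irx3, Nefh, Penk, Reln, Sh3bgr and Thrsp) passed without each animal in turn. Of 44 other called list members, those with the smallest p in their lists, 11 passed without each animal in turn. Another 15 (Atp5c1, Basp1, Cacng2, Epha7, Fgf13, Hk2, Nefl, Osmr, Ret, Rpl7, Ryr2, Scn8a, Slc44a1, Stmn4 and Vwf) passed in 1 of the 5 fits that left out 1 animal, and Psmd8 and Rps19 in none.

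**Figure D2:**
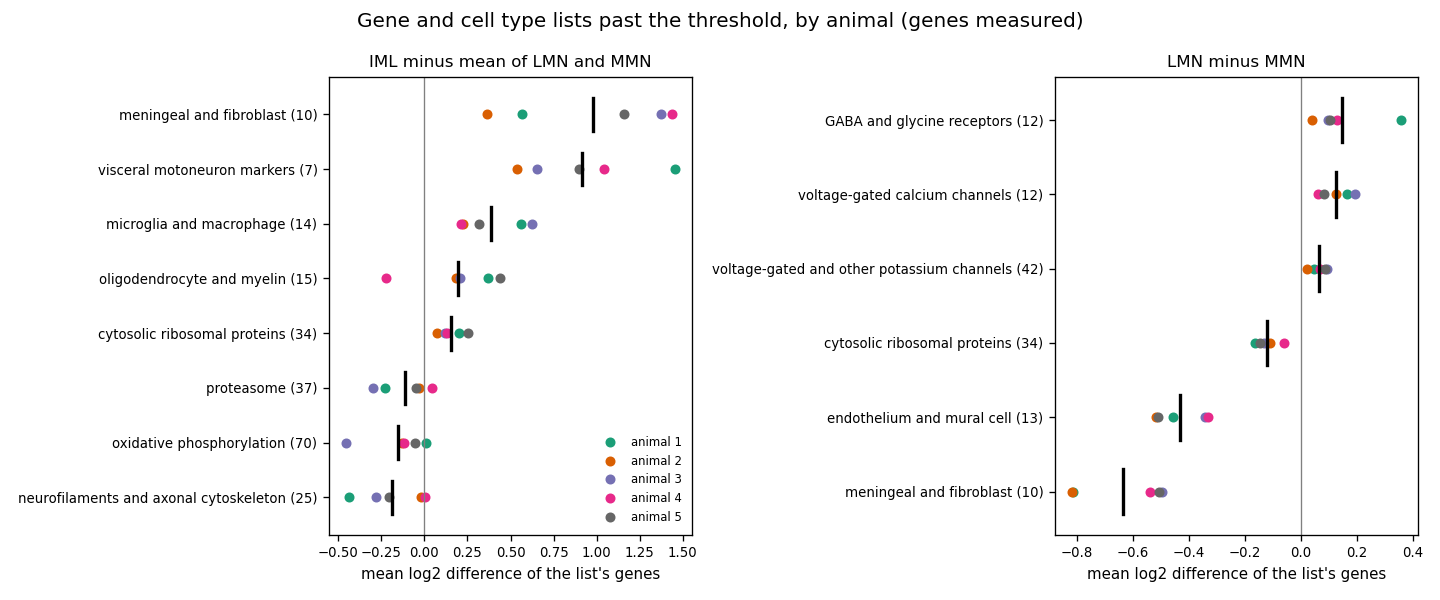
Mean log2 difference (horizontal axes) of the genes in each list past the camera threshold, with the number of measured genes in parentheses, for IML minus the mean of LMN and MMN (left) and LMN minus MMN (right). Points are the 5 animals and black bars their means. The meningeal and fibroblast list lay above 0 in 5 of 5 animals on the left, with a mean of 0.98, and below 0 in 5 of 5 on the right, with a mean of -0.64.

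IML and LMN gave the larger of the 2 pairwise counts that involve IML. S100a6 was higher by 2.12 ± 0.45, Anxa1 by 2.11 ± 0.36, Adcyap1 by 2.03 ± 0.22 (adjusted p = 0.000731), the large scaffold protein gene Ahnak by 1.92 ± 0.34 and Zic1 by 1.91 ± 0.26, each in 5 of 5 animals. With the meningeal and fibroblast covariate S100a6 turned to -0.76 and Ahnak to -0.54, and Anxa1 fell to 0.27 ± 0.79, while Adcyap1 (2.07 ± 0.60) and Zic1 (2.01 ± 0.72) stayed about as large with larger errors. None of the 5 was called in that model. Tpd52l1 (-1.59 ± 0.32), Bcl6 (-1.38 ± 0.24), Lgals1 (-1.22 ± 0.31), Lcp1 (-1.17 ± 0.30) and 1110008P14Rik (-1.16 ± 0.24) were the 5 lowest in IML. With the same covariate Tpd52l1 shrank to -0.80 ± 0.84 and Bcl6 to -1.02 ± 0.64. Lgals1 grew to -2.02 ± 0.81, Lcp1 to -1.83 ± 0.81 and 1110008P14Rik to -1.47 ± 0.66, and none of these 5 was called. Of these 10 genes, 5 (Adcyap1, Ahnak, Anxa1, Bcl6 and Zic1) passed without each animal in turn. Slc18a3 was called lower in IML than in LMN by -1.55 ± 0.42 (adjusted p = 0.0423), in 4 of 5 animals. That call was kept in 1 of the 5 fits that left out 1 animal, with differences from -2.05 to -1.20 and adjusted p from 0.0128 to 0.155. In all, 1116 probe sets differed, 678 higher and 438 lower in IML, of which 113 differed at least 2-fold. The count fell to 705 when the fit held the IML and LMN samples alone, to 601 with technical set 1 alone, to 135 without the animal as a block, to 468 without animal 3 and to 371 without animal 5, and was 699 without animal 1 and 734 without animal 4. With the meningeal and fibroblast covariate, which raised the median SE by 2.64 times, 0 were called by limma, against 1116 in the main model. The main model had 2923 at an unadjusted p under 0.05.

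IML and MMN differed in fewer probe sets. Adcyap1 was higher in IML by 1.59 ± 0.22 (adjusted p = 0.0148) and Reln by 1.39 ± 0.24. Ahi1, a gene of the primary cilium, was higher by 1.10 ± 0.12, D430019H16Rik by 0.89 ± 0.10 and the adhesion molecule gene Ncam1 by 0.87 ± 0.12. Cbln1, which encodes the synaptic organiser cerebellin, was lower in IML by -1.13 ± 0.16, with a mean of 8.62 ± 0.14 in IML, 8.84 ± 0.23 in LMN and 9.75 ± 0.45 in MMN. Irx3 (-0.95 ± 0.17), Sh3bgr (-0.91 ± 0.12), Thrsp (-0.75 ± 0.12) and Nefh (-0.65 ± 0.11) were also lower in IML than in MMN. Each of these 10 genes had the same sign in 5 of 5 animals. Slc18a3 differed by -1.11 ± 0.42 and was not called (adjusted p = 0.310). In all, 43 probe sets differed, 29 higher and 14 lower in IML, against 1533 at an unadjusted p under 0.05. The count was 6, all higher in IML, when the fit held the IML and MMN samples alone. It was 9 with technical set 1 alone and 58 with set 2 alone. Without the animal as a block 4 were called, without animal 1 the count was 13, without animals 3, 4 and 5 it was 0, 0 and 1, without the LMN sample of animal 2, a model chosen after seeing the data, it was 21, and none of the 10 genes passed without each animal in turn. With the meningeal and fibroblast covariate, and with Slc18a3 as a covariate, which raised the median SE by 1.59 and 1.25 times, 0 were called by limma. With the former the 10 genes kept their sign, from Cbln1, which fell to -0.65 ± 0.18, to Ahi1 at 1.34 ± 0.18.

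In the main model, which called 7 probe sets, the 2 somatic pools differed in few single genes. With only LMN and MMN in the fit 67 probe sets were called. Itih5, a hyaluronan-binding matrix protein, was lower in LMN than in MMN by a log2 difference of -0.997 ± 0.14 (adjusted p = 0.0228) and Igfbp3, an insulin-like growth factor binding protein, by -0.87 ± 0.10 (adjusted p = 0.00861), each in 5 of 5 animals. They were the only 2 genes that met the rule for named genes. Neither was called without the animal as a block or with the block as a random effect. The same held with the glial and with the meningeal and fibroblast covariate. With the latter Itih5 fell to -0.59 ± 0.15 and Igfbp3 to -0.78 ± 0.16. Itih5 passed in none of the 5 fits that left out 1 animal (differences from -1.07 to -0.92, adjusted p from 0.0534 to 0.164), and Igfbp3 passed in 1 (differences from -0.93 to -0.77, adjusted p from 0.0400 to 0.113). Bmp6, a bone morphogenetic protein, was called lower by -0.64 ± 0.07 with both means below the median over probe sets. It passed in 1 of the 5 fits that left out 1 animal (differences from -0.73 to -0.59, adjusted p from 0.00499 to 0.134) and was not called with technical set 1 alone, without the animal as a block or with the block as a random effect. Outside that rule, and chosen after their values were seen, 1 probe set of Gast, the gastrin gene, was called higher in LMN by 0.40 ± 0.05 (adjusted p = 0.00861) and 1 of the transcription factor Tbx2 by 0.37 ± 0.05 (adjusted p = 0.0208), each in 5 of 5 animals. Their LMN means of 5.48 for Gast and 5.57 for Tbx2 lay below the median over probe sets, and the brightest probe sets of Gast (0.05 ± 0.05) and Tbx2 (-0.000662 ± 0.05) were not called. Gast passed in 1 of the 5 fits that left out 1 animal (differences from 0.38 to 0.41) and Tbx2 in none (differences from 0.34 to 0.41). The other 2 called probe sets, 1 higher and 1 lower, had no single symbol. Over the brightest probe set of each gene, by moderated statistic, the next lowest were Fgl2 (-0.90 ± 0.15) and Mgp (-1.22 ± 0.21), and the highest were Fyttd1 (0.36 ± 0.06), Syt4 (0.91 ± 0.15), Ell2 (0.56 ± 0.10), Net1 (0.60 ± 0.11) and Clvs1 (0.66 ± 0.12). These 7 did not pass, with adjusted p from 0.0844 to 0.0937. Slc18a3 (0.44 ± 0.42), Prph (-0.04 ± 0.39), Isl1 (0.02 ± 0.10) and Nos1 (-0.04 ± 0.05) were not called. The Isl1 values in LMN lay below the median over probe sets, which limits what its difference shows. For Nos1 too, detection of the transcript is unknown.

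Between LMN and MMN 6 of the 34 lists were called, and none with an estimated correlation, where the smallest adjusted p was 0.194. All 10 meningeal and fibroblast markers were lower in LMN than in MMN, none was called singly, and 6 were lower when adjusted over the list alone. Their mean was -0.64 (camera adjusted p = 1.27e-07), with an adjusted p = 0.194 with an estimated correlation. Fmod, the matrix proteoglycan fibromodulin, differed by -0.73 ± 0.19 and was not called. Of 13 endothelial and mural cell markers, 10 were lower in LMN and none was called singly, with 4 lower when adjusted over the list alone. Their mean was -0.43 (adjusted p = 0.000425), with an adjusted p = 0.637 with an estimated correlation and a larger mean of -0.53 at an adjusted p of 0.141 when the dimmest 40% of probe sets were left out. In that list Acta2, the smooth muscle actin of vessel walls, differed by -2.56 ± 0.66 (adjusted p = 0.182) and Vwf by -0.98 ± 0.34. The 34 ribosomal protein genes had a mean of -0.12 (adjusted p = 0.000178), with an adjusted p = 0.194 with an estimated correlation, and none was called singly or when adjusted over the list alone. In the other direction, the 12 GABA and glycine receptor genes were higher in LMN by a mean of 0.15 (adjusted p = 0.00471), with an adjusted p = 0.637 with an estimated correlation and a mean of 0.09 (adjusted p = 0.0538) without animal 1. With the meningeal and fibroblast covariate their mean was 0.0355 (adjusted p = 0.450). Glrb, a glycine receptor subunit, differed by 0.45 ± 0.09, was not called over all probe sets (adjusted p = 0.101) and was the 1 gene higher when adjusted over the list alone. The 12 calcium channel genes (mean 0.12, adjusted p = 0.0146) and the 42 potassium channel genes (mean 0.06, adjusted p = 0.0460) were also higher in LMN as sets, each with an adjusted p = 0.664 with an estimated correlation and none called singly or when adjusted over the list alone. Kcna1 differed by 0.51 ± 0.14, Kcnab1 by 0.36 ± 0.09 and Cacng2 by 0.33 ± 0.13. The calcium channel call held in 16 of 23 alternatives, and ended without animal 1 or 3 (means 0.11 and 0.11, adjusted p = 0.0501 and 0.0686) and with technical set 2 alone (mean 0.10, adjusted p = 0.0872). It also ended with the fibroblast (mean 0.08, adjusted p = 0.195) and Slc18a3 (mean 0.10, adjusted p = 0.0868) covariates, and without dim probe sets, where the mean was larger at 0.16 (adjusted p = 0.141). The potassium channel call held in 7 of 23 alternatives. It ended without animal 1, 3, 4 or 5 (means from 0.05 to 0.07, adjusted p from 0.0501 to 0.0998), with technical set 2 alone (mean 0.04, adjusted p = 0.265) and after quantile normalization (mean 0.05, adjusted p = 0.0770). It also ended with each covariate (means 0.06, 0.04 and 0.05, adjusted p = 0.0966 for glial, 0.441 for fibroblast and 0.137 for Slc18a3). With the mean unchanged, it ended without the animal as a block (adjusted p = 0.0584) and with all 30 arrays (adjusted p = 0.0943), and without dim probe sets the mean was larger at 0.09 (adjusted p = 0.141).

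In all, 7 probe sets differed between LMN and MMN, 3 higher and 4 lower in LMN, against 1447 at an unadjusted p under 0.05, and 6 of 34 lists were called, against 0 with an estimated correlation (smallest adjusted p = 0.194). In the main test the smallest adjusted p among the other 28 lists was 0.109, for inhibitory interneuron markers. Without the animal as a block 0 probe sets were called by limma. When the fit held the LMN and MMN samples without the IML samples, 67 were called, 16 higher and 51 lower. The like fit of IML and MMN alone called 6, so the order of these 2 comparisons depended on the fit. In the fit of all pools the count for LMN against MMN was 1 without animal 1 and 0 without animal 2, 3 or 5.

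The animal accounted for a larger part of the spread between arrays than the pool did. The median share of the sum of squares per probe set was 41.7% for the animal, 7.23% for the pool, 19.7% for the pool by animal term and 24.6% for the technical array. The mean shares were 41.2%, 11.3%, 21.7% and 25.7%. The degrees of freedom alone would give mean shares of 13.8%, 6.90%, 27.6% and 51.7%, which are not to be set against the medians. The median technical SD was 0.13 on the log2 scale. Arrays of 1 sample correlated across probe sets with a median r of 0.996, arrays of 1 animal and different pools with 0.986, and arrays of 1 pool and different animals with 0.982. Probe sets are not independent replicates. After the animal means were removed, the first principal component held 41.0% of the variance.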

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

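No test in this part was chosen after the results were seen, and the values are given without an explanation. In 321 groups of 5 animals, 15 held 1 animal whose gap to the nearest of the others exceeded 0.71 of the group's range, or 4.67% of the groups. Chance flags about 1 in 20 such groups.

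The MMN sample of animal 2 was the far one in 4 of the 15 groups. In that sample Tac1 was high at 7.70 against 5.61 for the nearest of the others (gap 0.898 of the range). Igfbp3 was high at 10.02 (gap 0.764), Ncam1 was high at 9.63 (gap 0.823) and Fgf11 was low at 8.79 (gap 0.797). In LMN, animal 2 was also low in Fgf11, at 8.96 (gap 0.809), and high in Acta2, the smooth muscle actin, at 9.13 against 6.60 for the nearest (gap 0.848).

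Adcyap1 was high in the LMN sample of animal 4, at 9.11 against 7.21 for the nearest (gap 0.825). In the LMN sample of animal 1, Hoxd10 was high at 7.34 (gap 0.812) and Isl1 at 5.96 (gap 0.787). In the LMN sample of animal 5, Kcna1 was high at 10.23 (gap 0.723) and the mean of the cytosolic ribosomal protein list was low at 8.72 (gap 0.818). In IML, Lyz2 was high in animal 3 at 9.06 against 7.00 for the nearest (gap 0.837). Scg2 was high in animal 2 at 9.98 (gap 0.775). In animal 4, Stmn4 was low at 9.72 (gap 0.776) and Zic1 at 7.65 (gap 0.752).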

How the results depend on the processing

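Chosen after the data were seen were the meningeal and fibroblast covariate, the Slc18a3 covariate, the fit without suffixed probe sets and the fit without the LMN sample of animal 2. Counts are given for IML against somatic, IML against LMN, IML against MMN and LMN against MMN, where the main model called 686, 1116, 43 and 7 probe sets. Where no construction is named, the cause was not tested.

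Pairing by animal mattered in all 4 comparisons. With no replicate block the counts were 46, 135, 4 and 0 in limma. The last stood against 7 in the main model, which had 1447 at an unadjusted p under 0.05. With the block as a random effect IML against MMN gave 67 and LMN against MMN 4. With only the groups compared in the fit, which leaves fewer samples, the counts of the last 3 comparisons were 705, 6 and 67. For IML against somatic this is the main model. The count of LMN against MMN thus rose from 7 and exceeded that of IML against MMN. The main model used a common residual spread for all pools. Deviations of the same animal correlated with a median of 0.621 between LMN and MMN, 0.393 between IML and LMN and 0.416 between IML and MMN. Whether this accounts for the rise was not tested. Without each animal in turn the counts of the 4 comparisons ranged from 164 to 650, 371 to 935, 0 to 42 and 0 to 5. Technical set 1 alone gave 304, 601, 9 and 5, and set 2 alone gave 619, 713, 58 and 3. All 30 arrays in the fit gave 1574, 1833, 417 and 237. That fit entered the 2 technical arrays of a sample as separate observations with 1 shared correlation. Repeat arrays are not further animals, so these higher counts do not rest on more biological samples. The floor of 32 gave 282, 717 and 10 in the comparisons with IML. An adjusted p under 0.01 gave 146, 304, 7 and 4, and at least 2-fold 46, 113, 5 and 1, by construction. Stricter thresholds were not applied to single genes. Without the LMN sample of animal 2, IML against MMN gave 21. Median centring, quantile normalization, dim probe sets left out, trend and robust eBayes and suffixed probe sets left out kept all 4 counts within 1.5 times.

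The glial covariate gave 132, 210, 13 and 0 probe sets and raised the median SE by 1.39, 1.46, 1.16 and 1.09 times. With it the mean of the oligodendrocyte list turned to -0.0312, by construction, since its markers are in the covariate. The Slc18a3 covariate gave 10, 28 and 0 in the comparisons with IML and raised the median SE there by 1.45, 1.46 and 1.25 times. The meningeal and fibroblast covariate gave 0, 0, 0 and 0 in limma, against 686, 1116, 43 and 7 in the main model. The main model had 2574, 2923, 1533 and 1447 at an unadjusted p under 0.05. The covariate raised the median SE by 2.35, 2.64, 1.59 and 1.55 times. The design alone, where the marker mean overlaps with the pools, gives 2.38, 2.67, 1.61 and 1.57 times, by construction. Fewer calls with a covariate thus do not show by themselves that other tissue accounts for the differences. With the meningeal and fibroblast covariate the oxidative phosphorylation mean turned to 0.0311. In IML against somatic S100a6 turned to -0.53, Lum, a member of the covariate, to -0.59, Il6st to -0.0082 and Osmr to -0.20. In IML against LMN S100a6 turned to -0.76 and Ahnak to -0.54.

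Of the 34 lists, 8 were called between IML and somatic samples and 6 between LMN and MMN. These became 13 and 3 when dim probe sets were left out, and 0 and 0 in camera with an estimated correlation. Without each animal in turn they ranged from 8 to 11 and from 4 to 7. The pool's median share of the spread, 7.23%, was 8.03% without dim probe sets and 8.31% after quantile normalization. The median technical share, 24.6%, was 21.7% without dim probe sets. These arrays were used without detection calls, so signal over background is unknown and limits what low values show.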

Other observations

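Chosen after the results were seen were the tests of connective-tissue RNA, of a lower motoneuron share, of the MMN position and of interneurons, the counts of lists in splits within animals, and the meningeal and fibroblast covariate.

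Meningeal and fibroblast genes were higher in IML by a mean of 0.98 in 5 of 5 animals. The list held Igf2 at 12.73 in IML, 11.06 in LMN and 12.05 in MMN, and Col1a1 at 10.77, 9.29 and 9.69, and in LMN 9 of its 10 genes lay at or above the median over probe sets, with none in another list. A lower share of motoneuron RNA could raise the markers of other cell types. The list exceeded the lists of oligodendrocytes by 0.79 ± 0.64 (SD, n = 5), astrocytes by 0.81 ± 0.64, microglia by 0.59 ± 0.51, endothelium by 0.77 ± 0.48, inhibitory interneurons by 0.94 ± 0.64 and excitatory interneurons by 1.15 ± 0.66, each in 5 of 5 animals. It exceeded the red blood cell list by 0.45 ± 0.63, in 4 of 5 animals and within the spread. Without animal 3 it exceeded that list by 0.70 ± 0.33 (n = 4) and the oligodendrocyte list by 0.69 ± 0.69. A lower share need not raise all cell types equally, since the tissue beside each column may differ. The unequal rises therefore do not decide on a lower share, which stays open. Uneven amplification of 1 portion is argued against by the smaller shift of the 2 technical sets, 0.98. Connective-tissue RNA carried in with the captures may account for it and stays open: the members' residuals correlated with a median r of 0.130, at percentile 89.8 of 1000 random lists, across genes that are not independent, and a biological difference between the pools stays open as untested.

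On a scale from 0 at LMN to 1 at IML, MMN samples had a median position of 0.453, with each animal held out in turn (0.326 to 0.945). The scale used the 200 genes that differed most between IML and LMN in the other animals. On genes chosen in this way another pool tends to fall between the 2, so the position alone does not show that MMN is intermediate. A candidate explanation of the position, besides the choice of genes, is connective-tissue and vascular RNA that differs between the pools. After correction for the meningeal, fibroblast and endothelial score the median position was 0.465 (0.330 to 2.01, the highest in animal 2). It was above 0.2 in 5 of 5 animals and between 0 and 1 in 4. The mean of the fibroblast markers in MMN itself lay between those of LMN and IML. A partial correction could thus leave the position unchanged, so this test does not decide on that RNA. The pools' own identity stays open as an untested explanation.

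The visceral motoneuron list was higher in IML by 0.92 ± 0.12 (SE). Neighbouring interneurons in the IML captures could carry Penk and Tac1. With the score of 12 interneuron genes in the model the shift was 0.94 ± 0.12, but the score itself differed by only -0.03 ± 0.15 (SD, n = 5) between IML and somatic samples, so it had nothing to correct and that model decides nothing. Interneurons in the captures stay open, and preganglionic motoneurons themselves were not tested.

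Other splits of the samples were drawn to ask whether chance can be excluded. For IML against somatic samples it can: 1 of 100 splits, the real one, gave 686 probe sets, and the highest other gave 610, in a split that holds 4 of the 5 IML samples on the same side. Within animals the real split was again the 1 of 100, with 270 in the highest other, which set LMN against the rest. For the 3 comparisons of 2 pools, the real split was the 1 of 100 as large for IML against LMN (1116, highest other 443), for IML against MMN (43, highest other 4) and for LMN against MMN (7, highest other 1). These 100 splits ignore the animal and break the pairing the model uses, so they do not settle it. Within animals the real split was the 1 as large of 16, with highest others of 0, 1 and 0, but 16 splits are too few for a share under 0.05. For the 8 lists of IML against somatic samples chance cannot be excluded: 18 of 100 splits within animals gave as many (highest other 11), and 17 of 100 that ignore the animal (highest other 12). For the 6 lists of LMN against MMN, 26 of 100 splits that ignore the animal gave as many (highest other 10), and within animals 3 of 16 (highest other 7), where 16 splits are too few for a share under 0.05.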
